A study of Mus musculus with 10 samples.

How the data were processed

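The series holds 10 samples of mouse duodenal organoids, of which 4 GRO-seq libraries (2 in WENRC and 2 in ENRI medium) and 2 H3K27me3 ChIP-seq libraries (1 per medium) were compared. Per the labels, GRO-seq used 14 PCR cycles, and ChIP-seq reads were 50 bp long. The input DNA and histone H3 samples were not analysed here, other than through the authors' peak calls against input. Groups came from the sample titles, which number the mice 1 and 2 in both media.

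Transcription signal was deposited as scaled reads per RefSeq transcript in build mm9. Per the file headers, the authors counted reads over whole gene bodies with HOMER and compared the media with edgeR, with the first library of each medium as batch 1 and the second as batch 2. The labels name FastQC, Bowtie, Bowtie2 and HOMER 4.3. Each of the 4 deposited columns summed to 20.0M over 33022 transcripts although the header states no adjustment, and all low values tested were whole multiples of 1 step per library (100% within a tolerance of 0.1), so whole reads were recovered by dividing by that step. Over all transcripts these were 25839484 and 29128101 reads in WENRC and ENRI of batch 1, and 9245915 and 15787828 in batch 2. The most read gene, the ribosomal precursor Rn45s, took 1.52% to 3.35% of reads. A column could be assigned to its medium and batch but not to a mouse, and "batch" is the number in the header. The strand setting of the counting and the base of the coordinates are not stated. The 4 deposited RPKM columns were not used here. Log2 fold changes in the authors' deposited table, positive where ENRI was higher, and their p-values and FDR came, per the file headers, from edgeR's likelihood ratio test with batch as a term.

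H3K27me3 peaks were called by the authors with HOMER in each library alone against input DNA of the same medium, requiring 4-fold enrichment over input and over the local 10000 bp at a p of 0.0001. The broad lists joined windows of 1000 bp up to 10000 bp apart at an FDR of 0.001, and the narrow lists used windows of 500 bp and a distance of 1000 bp at a Poisson p of 0.001, per the file headers. The fold over input in the deposited lists is the ratio of scaled ChIP tags to input tags, and the deposited score is the tag count of the best window in a region. Tags in peaks, per the file headers, were 4.45% and 3.44% of all tags for the broad lists and 6.99% and 8.55% for the narrow lists, in WENRC and ENRI.

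RPKM was computed as scaled reads per kb of transcript per column total. For each of 24016 gene symbols (20617 protein coding, 390 with more than 1 genomic copy) the longest transcript was kept. Genes with at least 0.5 RPKM in at least 2 libraries were tested with limma (version 3.58.1, R 4.3.3, moderated with a mean trend) on log2 RPKM with a pseudocount of 0.5, without a block, at a Benjamini-Hochberg adjusted p of 0.05. The replicate block was an alternative, since the titles number the same mice in both media, and deviations from the group means of paired libraries correlated at 0.0126 across genes. With 2 libraries per group, regrouping the libraries was not used as a test. Fixed lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, and by camera with an estimated correlation as an alternative. A further alternative, fry, tests a list against no change and not against other genes. The promoter was 2 kb either side of the transcription start, and 1 bp of overlap with a broad region marked it. Classes were compared by camera and with 10000 random sets matched on mean log2 RPKM. The random sets treat genes as independent, so their range is too narrow where genes of a class move together. Lists in classes were compared by Fisher's exact test, two-sided, against 24016 genes. Binomial intervals are exact (Clopper-Pearson, 95%), and ratios of reads have exact binomial intervals. The intervals on reads cover counting error only, and may be too narrow even for that, since PCR reads are not independent molecules. The intervals on shares of peaks treat regions as independent draws.

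The tests, 24 gene lists, 50 pairs of a result and an alternative, and the rule for named genes were set before the data were examined. The alternatives were pseudocounts, filters, scalings, the block, other tests (edgeR 4.0.16, DESeq2 1.42.0), each library left out (the lone library of a medium being assumed to vary like the other pair), the narrow peak lists, score and overlap limits and promoter width. Added later were 7 such pairs and 2 lists, named in the closing section. The rule named up to 10 genes past the test per direction by size of change, leaving out clone-like names, up to 4 per list, a set of genes fixed by name and up to 8 promoters per medium by peak score, 128 genes in all, of which the text gives a part. Tff3, Fcgbp, Clca1, Slc15a1, Sepp1, Smoc2, Ephb2, Tcf7, Wif1, Tnfrsf19, Dlx1, Dlx2, Dlx5, Dlx6, 4930474M22Rik, the microRNA genes, Asns, Atf5, Psat1, Ddit3, Cebpg, Cebpb, Slc3a2, Reg1 and Reg3a are outside the rule and were chosen after their values were seen. The fixed lists were intestinal stem cell, Wnt target, enterocyte, Paneth, goblet, enteroendocrine and tuft cell, cell cycle, PRC2, PRC1, H3K27 demethylase and trithorax, Hox, developmental transcription factor, Cdkn2 locus and cell cycle inhibitor, Notch, fatty acid oxidation and PPAR target, cholesterol synthesis, ribosome biogenesis, regenerative, immediate early, interferon, mesenchymal, immune and endothelial genes. The pipeline was tested on simulated data with the 2 against 2 design. Where simulated genes varied as with the block, limma called 0% of 45 genes changed by 1 log2 unit, 61.9% of 42 changed by 2 and 91.1% of 56 changed by 3, and 8 unchanged genes, and edgeR's quasi-likelihood test called 3.08%, 57.6% and 89.6%, and 13 unchanged genes. Where they varied as without it, limma called 0% at each size and 0 unchanged genes, and edgeR's test called 3.17%, 18.5% and 63.1%, and 5 unchanged genes. Few simulated genes were changed (45, 42 and 56 of 12133 in the first limma fit), whereas 4520 of 11602 real genes had an unadjusted p under 0.05 (limma). Adjusted calls depend on that share, so these rates do not give the sensitivity of the real comparison. In the first limma fit, changes of 2 and 3 had median estimates of 1.55 and 2.24. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used for the rest.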

Results

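Nascent transcription was measured by global run-on sequencing (GRO-seq), which captures the RNA that engaged polymerases extend in isolated nuclei, in organoids grown from mouse duodenum. The organoids were kept in 2 media. WENRC, the stem cell medium of the labels, contained Wnt3A, EGF, Noggin, R-spondin and the Wnt pathway agonist CHIR-99021. ENRI, their enterocyte differentiation medium, lacked Wnt3A and CHIR-99021 and contained IWP-2, which blocks Wnt secretion. Each medium had 2 GRO-seq libraries, numbered here by the batch that the authors' file header gives them. Reads recovered over 1 transcript per gene were 16302417 in WENRC batch 1, 18368297 in ENRI batch 1, 5868984 in WENRC batch 2 and 10245678 in ENRI batch 2. H3K27me3, the histone mark written by Polycomb repressive complex PRC2, was mapped by ChIP-seq in 1 library per medium, with 31.4M tags in WENRC and 29.8M in ENRI, per the file headers. The series title concerns PRC2 in the homeostasis of the intestine, and the comparisons below ask which genes and which marked promoters differ between the media.

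Reg3b and Reg3g, which encode secreted antimicrobial lectins, and their relative Reg3d rose in ENRI organoids. Reg3b went from 0.0434 ± 0.00219 RPKM in WENRC to 38.5 ± 9.85 RPKM in ENRI (mean ± SD, n = 2 libraries per medium), Reg3d from 0.0607 ± 0.0676 to 5.97 ± 1.02 and Reg3g from 0.178 ± 0.0418 to 3.34 ± 0.458. Muc2, the main gel-forming mucin of goblet cells, rose from 0.126 ± 0.0289 to 2.15 ± 0.172 RPKM, and Zg16, a secretory granule protein of goblet cells, from 0.115 ± 0.0782 to 17.3 ± 6.14 RPKM (n = 2). Stc2, which encodes the secreted glycoprotein stanniocalcin, fell from 11.4 ± 0.941 to 0.790 ± 0.172 RPKM, and Chac1, a glutathione-degrading enzyme, from 8.31 ± 1.54 to 0.491 ± 0.0324 RPKM (n = 2). Slc7a5, a transporter of large neutral amino acids, fell from 6.08 ± 0.606 to 0.876 ± 0.0140 RPKM, while the lipase relative Pnliprp2 rose from 0.166 ± 0.0139 to 2.09 ± 0.0520 and Ccdc152 from 0.445 ± 0.0823 to 4.08 ± 0.0870 RPKM (n = 2).

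Among 11602 genes tested with limma, 17 passed a Benjamini-Hochberg adjusted p of 0.05, 7 higher and 10 lower in ENRI, and all 17 had the same direction in both batches. Their adjusted p lay between 0.0374 and 0.0484. The log2 changes, fitted with a pseudocount of 0.5 RPKM, were 6.14 ± 0.24 (SE) for Reg3b, 4.82 ± 0.30 for Zg16, 3.52 ± 0.18 for Reg3d, 2.28 ± 0.13 for Ccdc152, 2.08 ± 0.12 for Muc2 and 1.96 ± 0.11 for Pnliprp2. They were −3.21 ± 0.19 for Stc2, −3.14 ± 0.18 for Chac1 and −2.25 ± 0.15 for Slc7a5. Reg3b, Reg3d, Zg16 and Reg3g had 4, 4, 9 and 15 reads in the WENRC libraries together, so their fitted changes rest on the pseudocount. From reads alone the ENRI level was 825 times the WENRC level for Reg3b (exact 95% interval for counting error 322 to 3029), 151 times for Reg3d (58.7 to 555), 132 times for Zg16 (69.3 to 289) and 20.9 times for Reg3g (12.5 to 37.8). Muc2, Pnliprp2 and Ccdc152 also had WENRC means under the pseudocount, which shrinks their fitted changes. From reads their ENRI levels were 15.6, 12.9 and 8.66 times the WENRC levels. The number of calls moved with the libraries kept and with the scaling. With 1 library left out, the lone library of its medium was assumed to vary like the pair of the other medium, so these counts rest on the spread of that pair. Without the WENRC library of batch 1 or that of batch 2, 0 genes passed (limma, 1685 and 1358 genes at an unadjusted p under 0.05), without the ENRI library of batch 1 5795 passed, and without that of batch 2 685. Quantile normalization, which moved the median log2 change of all tested genes from −0.21 to −0.04, gave 507 higher and 422 lower genes, and median centring, with a median of −0.06, gave 7 and 5. With the batch as a replicate block, so that libraries were paired, 0 genes passed in limma (3841 at an unadjusted p under 0.05), while edgeR's quasi-likelihood test gave 0 without and 193 with the block and DESeq2 gave 2095 without it. The balance of directions also turned with the method, with 1538 higher and 557 lower genes in DESeq2 and 157 and 36 in edgeR with the block, but 640 and 1255 in limma with a filter on at least 10 recovered reads and 1809 and 3986 without the ENRI library of batch 1. In the authors' deposited table, 1923 rows were higher and 1044 lower in ENRI at an FDR under 0.05.

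In build mm9, the Reg genes lie on chromosome 6, with Reg3b (NM_011036) at 78320879 to 78323460, Reg3d (NM_001161741) at 78325868 to 78328859 and Reg3g (NM_011260) at 78416262 to 78418868. Chromosome 7 holds Zg16 (NM_026918) at 134193670 to 134195491 and Muc2 (NM_023566) at 148876239 to 148940599. Stc2 (NM_011491) lies on chromosome 11 at 31259441 to 31270061, Chac1 (NM_026929) on chromosome 2 at 119176978 to 119180062 and Slc7a5 (NM_011404) on chromosome 8 at 124405046 to 124431586. Pnliprp2 (NM_011128) lies on chromosome 19 at 58834213 to 58852024. Ccdc152 (NM_001166063), on chromosome 15 at 3230627 to 3253526, ends 119 bp from Sepp1, the gene of the plasma selenium carrier selenoprotein P, on the other strand. Sepp1 was higher in ENRI by 3.17 ± 0.24 (log2, SE) with an adjusted p of 0.0518 (limma), so it did not pass. The strand setting of the read counting is not recorded, and reads of such neighbours and of overlapping genes cannot be separated.

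The other 7 genes that fell are outside the rule for named genes and were chosen after their values were seen. The uncharacterised transcript 4930474M22Rik fell by 2.41 ± 0.14 (log2, SE) and overlaps the stem cell marker Smoc2 on the other strand, which had a log2 change of −2.15 ± 0.25 with an adjusted p of 0.0560 (limma). The microRNA genes Mir5621, Mir6937, Mir3474, Mir6998, Mir7052 and Mir3081 had at most 5 reads in any WENRC library and 0 in both ENRI libraries. Each lies inside a host gene on the same strand, and none of the host genes passed the test, with Boc, the host of Mir3081, below the filter. For Mir3474, Mir6998, Mir7052 and Mir3081 the exact 95% interval of the ratio for counting error reached 1.18, so a difference was not detectable from the reads.

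**Figure D1:**
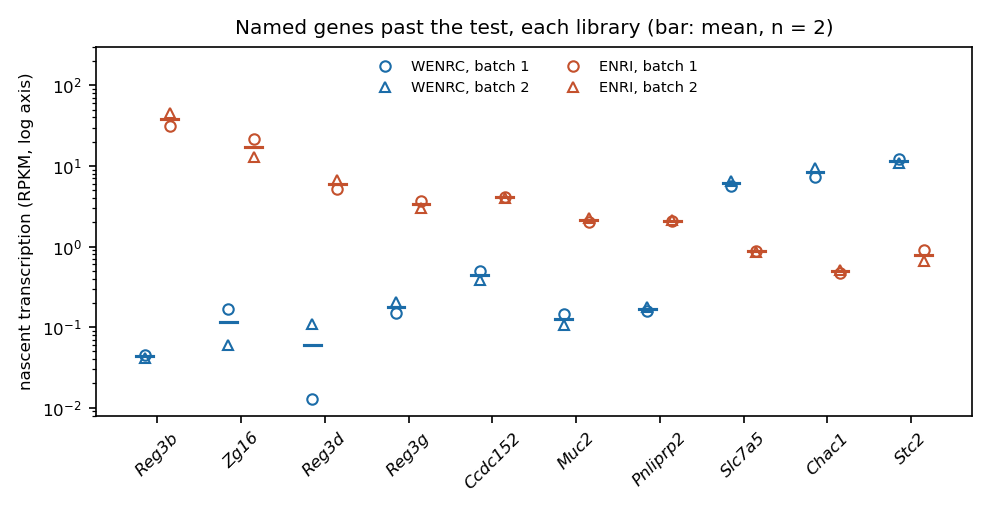
Nascent transcription (RPKM, log axis) of the 10 named genes past the test in each GRO-seq library, with circles for batch 1, triangles for batch 2 and a bar at the mean of each medium (n = 2). Reg3b had 31.5 and 45.5 RPKM in ENRI against 0.0449 and 0.0418 in WENRC, and Stc2 had 0.912 and 0.668 RPKM in ENRI against 12.1 and 10.8 in WENRC.

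Genes of mature enterocytes were higher in ENRI as a group, which addresses whether the differentiation medium moved organoids along the crypt to villus axis. Of 35 tested members of the enterocyte list, 33 were higher in ENRI, with a median log2 change of 2.36. Apoa1, an apolipoprotein of lipid export, had 3.03 ± 1.13 RPKM in WENRC and 218 ± 68.4 RPKM in ENRI (n = 2), and its relative Apoa4 had 6.91 ± 4.86 and 270 ± 22.6 RPKM. The villus keratin Krt20 had 1.38 ± 0.841 and 24.7 ± 1.80 RPKM, the fatty acid binding protein Fabp1 3.05 ± 2.01 and 34.1 ± 20.5 RPKM, and the brush border phosphatase Alpi 7.49 ± 6.26 and 48.7 ± 3.62 RPKM. In limma 0 members passed over all genes, 30 had an unadjusted p under 0.05, and 30 rose when adjusted over the list alone. DESeq2 called 33 members higher, and edgeR's quasi-likelihood test 0 without and 9 with the replicate block. The list passed camera, limma's set test (adjusted p = 8.35e-20 with a preset correlation of 0.01, adjusted p = 0.641 with an estimated correlation). Its median was 1.61 in batch 1 and 2.98 in batch 2, and the authors' deposited table had 32 members higher at an FDR under 0.05.

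Intestinal stem cell genes and Wnt targets were lower in ENRI. The median log2 change was −1.29 in each list, with 23 of 25 stem cell genes and 15 of 16 Wnt targets lower. The 2 lists share 8 tested genes. Lgr5, the receptor that marks crypt base stem cells, had 2.41 ± 0.638 RPKM in WENRC and 0.168 ± 0.0370 RPKM in ENRI (n = 2, adjusted p = 0.0540, limma). The Wnt feedback gene Axin2 had 9.93 ± 2.78 and 0.790 ± 0.239 RPKM, the stem cell transcription factor Ascl2 1.61 ± 0.233 and 0.280 ± 0.118 RPKM, and the stem cell marker Olfm4 1.82 ± 0.429 and 0.227 ± 0.254 RPKM. In limma 0 stem cell genes and 0 Wnt targets passed over all genes, 15 and 10 had an unadjusted p under 0.05, and 12 and 10 fell when adjusted over the list alone. DESeq2 called 11 stem cell genes lower and 1 higher, and 5 Wnt targets lower. With the replicate block, edgeR's quasi-likelihood test called 4 and 2 lower, and without it 0 of either. Both lists passed camera with the preset correlation (stem cell adjusted p = 2.63e-04, Wnt target adjusted p = 0.00110), with adjusted p = 0.641 and adjusted p = 0.700 with an estimated correlation. The batch medians were −0.87 and −1.59 for stem cell genes and −0.60 and −1.70 for Wnt targets. The authors' deposited table had 17 stem cell genes and 8 Wnt targets lower at an FDR under 0.05.

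Cell cycle and ribosome biogenesis genes were also lower in ENRI, and fatty acid oxidation and PPAR target genes were higher. All 29 tested cell cycle genes were lower, with a median log2 change of −0.99. The proliferation marker Mki67 had 6.38 ± 0.405 RPKM in WENRC and 2.29 ± 0.594 RPKM in ENRI (n = 2), and the cyclin gene Ccna2 had 4.37 ± 0.193 and 2.05 ± 0.00273 RPKM. Of 20 ribosome biogenesis genes, 19 were lower, with a median of −0.96, among them the nucleolar genes Npm1 (−1.63 ± 0.47, SE) and Ncl (−1.33 ± 0.47). Of 21 fatty acid oxidation and PPAR target genes, 18 were higher, with a median of 0.91, among them the lipid droplet protein Plin2 (1.64 ± 0.35) and the lipase inhibitor Angptl4 (1.59 ± 0.34). In limma 0 members of these 3 lists passed over all genes, while 25 cell cycle genes, 15 ribosome biogenesis genes and 12 fatty acid genes had an unadjusted p under 0.05. Adjusted over the list alone, 25 cell cycle genes and 13 ribosome biogenesis genes fell and 9 fatty acid genes rose. DESeq2 called 15, 4 and 13 members in the same directions, and edgeR's quasi-likelihood test called 0 with or without the block. With the preset correlation the lists passed camera (adjusted p = 2.80e-07 for cell cycle, 7.79e-04 for ribosome biogenesis and 2.80e-07 for fatty acid genes), with adjusted p = 0.656, adjusted p = 0.751 and adjusted p = 0.641 with an estimated correlation. The medians in batch 1 and batch 2 were −0.83 and −1.17 for cell cycle, −0.67 and −1.22 for ribosome biogenesis and 0.47 and 1.20 for fatty acid genes. The authors' deposited table had 16 cell cycle genes and 6 ribosome biogenesis genes lower and 13 fatty acid genes higher at an FDR under 0.05.

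Goblet cell genes were higher in ENRI as a group, with a median log2 change of 0.72 over 8 tested members, 6 of them higher. Muc2 and Zg16 rose over all genes tested, and adjusted over the list alone 4 rose and 1 fell. Tff3, Fcgbp and Clca1 are outside the rule for named genes and were chosen after their values were seen. The trefoil peptide gene Tff3 was higher by 1.18 ± 0.30 (log2, SE) and the mucus component Fcgbp by 1.88 ± 0.47, whereas Clca1, another secreted goblet cell protein, was lower at −0.85 ± 0.15. Atoh1, the transcription factor that specifies secretory cells, differed by 0.05 ± 0.20, less than its error, and its sign changed without the WENRC library of batch 1 (−0.17) or the ENRI library of batch 2 (−0.05). The list passed camera (adjusted p = 0.00777 with the preset correlation, adjusted p = 0.641 with an estimated correlation) and did not pass without the filter on low values (adjusted p = 0.0720). The batch medians were 0.81 and 0.64, and the authors' deposited table had 4 members higher and 1 lower at an FDR under 0.05.

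Genes of PRC2 itself were lower in ENRI in 10 of 11 cases, but the list did not pass camera (median log2 change −0.52, adjusted p = 0.0676). The median of all tested genes was −0.21, and 65.3% of genes without a promoter region were lower. Ezh2, the catalytic subunit, had 1.78 ± 0.0997 RPKM in WENRC and 0.846 ± 0.275 RPKM in ENRI (n = 2), a log2 change of −0.77 ± 0.18 (SE). The core subunits Suz12 and Eed differed by −0.62 ± 0.18 and −0.44 ± 0.14, and the histone-binding subunit Rbbp7 by −0.69 ± 0.15. Ezh1, the alternative catalytic subunit, differed by −0.16 ± 0.13, near the median of all tested genes, and by 0.06 after quantile normalization, which moved that median to −0.04. In limma 0 members passed over all genes or adjusted over the list alone, 8 had an unadjusted p under 0.05, and edgeR's quasi-likelihood test and DESeq2 called 0. The list passed after quantile normalization (adjusted p = 0.0496) and without the filter on low values (adjusted p = 0.0126), and adjusted p = 0.751 was found with an estimated correlation.

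The lists of other cell types and pathways did not pass camera. The adjusted p was 0.540 for Paneth cell, 0.125 for enteroendocrine, 0.458 for PRC1 subunit, 0.540 for H3K27 demethylase and trithorax, 0.494 for Hox, 0.812 for Cdkn2 locus and cell cycle inhibitor, and 0.126 for Notch pathway genes. It was 0.494 for cholesterol synthesis and 0.0857 for immediate early genes, where it was 0.00247 without the WENRC library of batch 2 and 0.0242 without the ENRI library of batch 1. For Hox genes it was 0.0493 without the WENRC library of batch 2. These fits take the spread from the medium that kept both libraries. The adjusted p was 0.515 for interferon response genes. Their camera direction was up relative to other genes, with a median of −0.06 and a mean of −0.03, against a median of −0.21 over all tested genes. The Paneth cell gene Lyz1 differed by −0.57 ± 0.69 (0.28 without the ENRI library of batch 1) and the enteroendocrine gene Chga by 0.22 ± 0.13 (log2, SE). Cdkn2b, an inhibitor of cyclin-dependent kinases, differed by 1.10 ± 0.21, and its neighbour Cdkn2a stayed below the filter at 0.229 ± 0.109 RPKM in WENRC and 0.401 ± 0.296 RPKM in ENRI (n = 2). Too few members were tested for the tuft cell (2), developmental transcription factor (3), mesenchymal cell (1), immune cell (1) and endothelial cell (0) lists. The mesenchymal and immune genes above the filter were Acta2, at −0.37 ± 0.23, and Cd68, at −1.38 ± 0.23.

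Regenerative or fetal epithelium genes differed between the media in opposite directions in the 2 batches. All 14 tested members were higher in ENRI than in WENRC in batch 1 (median log2 change 1.17) and lower in batch 2 (median −2.18). Ctgf, a target of the YAP pathway, had 25.7 and 0.606 RPKM in the ENRI libraries of batch 1 and batch 2 against 3.21 and 5.54 RPKM in WENRC, and the calcium-binding protein gene S100a6 had 29.2 and 1.58 against 5.19 and 4.84 RPKM. The list did not pass camera (adjusted p = 0.812), whose direction was up although the median over both batches was −0.48 and the mean −0.37. With the ENRI library of batch 2 left out the direction was up (adjusted p = 2.96e-05), and with that of batch 1 left out it was down (adjusted p = 0.00263), where the spread came from the WENRC pair alone. Across all tested genes, the 2 WENRC libraries correlated at r = 0.949 and the 2 ENRI libraries at r = 0.874, where genes are not independent replicates. Between the media, the libraries of batch 1 correlated at r = 0.865 and those of batch 2 at r = 0.679. The changes in batch 2 were larger than those in batch 1, with an SD over genes of 0.97 against 0.59, and 79.5% of tested genes had the same sign in both.

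**Figure D2:**
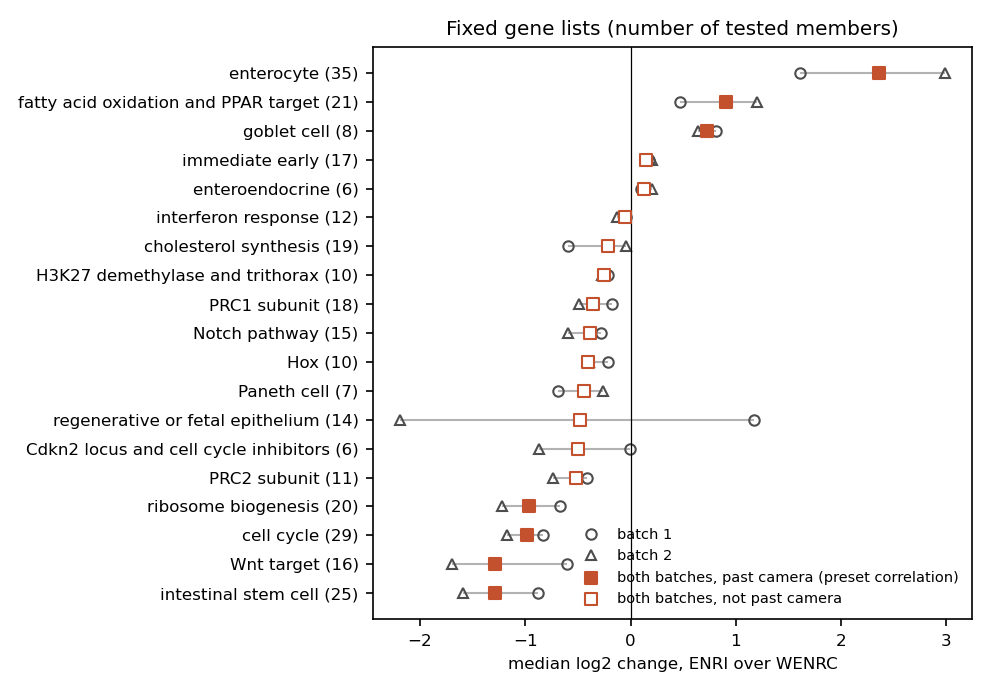
Median log2 change (ENRI over WENRC) of each gene list with at least 5 tested members, as a square over both batches, a circle in batch 1 and a triangle in batch 2; filled squares passed camera with the preset correlation. Enterocyte genes lie highest at 2.36, stem cell genes and Wnt targets lowest at −1.29, and the regenerative list spans 1.17 in batch 1 to −2.18 in batch 2.

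H3K27me3 covered 22.4 Mb in 5009 broad regions in WENRC and 21.3 Mb in 6094 broad regions in ENRI, which addresses how far the mark lies at the same places in both media. Of the WENRC broad regions, 37.1% overlapped an ENRI region (exact 95% interval 35.8 to 38.4), and of the ENRI broad regions 30.3% overlapped a WENRC region (29.1 to 31.4). Regions moved along the genome overlapped in 1.98% and 1.60% of cases, the means of 100 shifts. In the authors' narrow lists, 33499 WENRC peaks covered 38.2 Mb and 55544 ENRI peaks 55.6 Mb, and 40.0% (39.5 to 40.6) and 24.4% (24.1 to 24.8) overlapped. Shared broad regions covered 11.1 Mb. In 1838 matched pairs of broad regions, the median fold over input in the authors' deposited lists was 5.18 in WENRC and 4.87 in ENRI. With 1 library per medium there is no replicate error, the intervals only treat regions as independent draws, and a comparison of these lists is one of 2 libraries. With the same number of top-scoring broad regions from each list, the shares were 33.6% and 33.4%.

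Promoters of developmental regulators carried H3K27me3 in both media. All 39 Hox genes, which pattern the body axis, and 55 of 66 developmental transcription factors had a broad region within 2 kb of the transcription start in both libraries (for the transcription factors, Fisher's exact test, two-sided, adjusted p = 2.30e-54 against 24016 genes). The 39 Hox genes lie in clusters and shared 5 broad regions in each medium, so they are not independent promoters and no p is given for them. The 55 transcription factors lay in 53 regions in each medium, with Dlx1 and Dlx2 in 1 region and Dlx5 and Dlx6 in another. A broad promoter region in both media was also listed for Cdkn2a, the cell cycle inhibitor locus, for Atoh1, and for 8 of 22 enteroendocrine genes (adjusted p = 4.98e-04) and 6 of 14 mesenchymal genes (adjusted p = 0.00144). Of 26 Wnt targets, 7 had a promoter region in ENRI only (Fisher's exact test, adjusted p = 9.38e-05), namely Axin2, Ascl2, Ccnd1, Ephb2, Tcf7, Wif1 and Tnfrsf19. Another 2 had a region in WENRC only (adjusted p = 0.813). Of 30 stem cell genes, 4 had a region in ENRI only (adjusted p = 0.0948), and 10 did so in the narrow lists (adjusted p = 3.90e-05), Lgr5 and Olfm4 among them. Of 18 regenerative genes, 3 had a region in ENRI only (adjusted p = 0.117), and 5 did so in the narrow lists (adjusted p = 0.0243). At Ascl2 the ENRI region spanned 150152617 to 150157073 on chromosome 7 with 6.18-fold enrichment over input in the authors' deposited list, and at Axin2 108782639 to 108786912 on chromosome 11 with 5.09-fold enrichment. Neither WENRC list held a promoter peak at these genes. Of 36 enterocyte genes, 35 had no broad promoter region in either medium, and the exception, named after its values were seen, was the peptide transporter Slc15a1, with a region in WENRC only at 121901012 to 121905645 on chromosome 14. Slc15a1 transcription was 0.0809 ± 0.0139 RPKM in WENRC and 2.59 ± 0.981 RPKM in ENRI (n = 2, log2 change 2.37 ± 0.25, adjusted p = 0.0560, limma). None of the 29 cell cycle genes had a broad promoter region. Over all 24016 genes, 86.9% had none. For a region in both media, neither the enterocyte nor the cell cycle list was shown to differ from all genes (Fisher's exact test, adjusted p = 0.530 and adjusted p = 0.744).

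Over all 24016 genes, 1464 promoters had a broad region in both media, 1052 in WENRC only, 640 in ENRI only and 20860 in neither. The promoters with the highest peak scores were those of Adarb1, Adcyap1r1, Gnao1, Gpr124, Hey1, Ldlrad4, Matn4 and Podxl in WENRC only, and of Atp8b2, Car11, Cyp27b1, Fhod1, Gnal, Myo5a, Slc9a5 and Tead4 in ENRI only, where Fhod1 and Slc9a5 share 1 region. Cyp27b1, the enzyme that activates vitamin D, had 1.98 ± 0.0383 RPKM in WENRC and 0.355 ± 0.0691 RPKM in ENRI (n = 2), and the formin gene Fhod1 2.49 ± 0.102 and 1.28 ± 0.0312 RPKM. Podxl, a sialomucin gene, had 0.724 ± 0.0391 and 0.457 ± 0.0594 RPKM. The medium-specific classes depended on the peak list. Of the 1052 promoters in WENRC only, 749 were in both media in the narrow lists and 251 in WENRC only, and of the 640 in ENRI only, 357 were in both and 251 in ENRI only. Among the 16 top-scoring genes, the narrow lists gave the same class for Ldlrad4 and Podxl and the opposite one for Gnal and Tead4.

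Genes with H3K27me3 at the promoter were transcribed at low levels in every library. The median RPKM, averaged over the 4 libraries, was 0.0270 ± 0.0104 (SD, n = 4) for genes marked in both media, 0.0390 ± 0.010 for WENRC only, 0.0508 ± 0.0150 for ENRI only and 0.487 ± 0.106 for neither. Genes marked in ENRI only had a median of 0.0576 RPKM in WENRC and 0.0440 RPKM in ENRI (means of 2 libraries), and genes marked in WENRC only had 0.0392 and 0.0387 RPKM. By batch, the ENRI-only class had 0.0419 in WENRC and 0.0441 in ENRI in batch 1, and 0.0732 and 0.0440 in batch 2, so its lower ENRI mean came from WENRC batch 2, the library with the fewest reads. These are descriptions within each library, and genes are not replicates. In the narrow lists, WENRC only had a median of 0.0971 RPKM and ENRI only 0.0356 RPKM, so the order of these classes was the opposite.

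Among genes above the filter, those marked in ENRI only were lower in ENRI, which addresses whether a mark present in 1 medium goes with lower transcription in that medium. Of the 640 genes of this class, 22.5% were tested. Of these 144 genes, 84.0% were lower, with a median log2 change of −0.62, against 65.3% of the 11095 genes with a region in neither medium. A gene can pass the filter through the 2 WENRC libraries alone, which may favour lower ENRI values and was not tested. Without the filter the class median was −0.03, against −0.04 over all genes, and most of the class then lay far under the pseudocount. With a filter at 1 RPKM the class median was −0.80 over 83 genes, against −0.20 over all genes tested. Axin2 (9.93 ± 2.78 RPKM in WENRC, 0.790 ± 0.239 RPKM in ENRI, n = 2) belongs to the ENRI-only class. So do Cyp27b1 (log2 change −1.54 ± 0.12, SE), Ascl2 (−1.44 ± 0.17), Fhod1 (−0.75 ± 0.13) and Chga (0.22 ± 0.13). Ctgf, also of this class, changed by 2.82 in batch 1 and −2.45 in batch 2. By the narrow lists Cyp27b1 and Fhod1 were marked in both media. The median was −0.37 over 192 genes marked in both media, −0.11 over 171 marked in WENRC only and −0.20 over the genes in neither. In limma 0 genes of the 3 marked classes passed, and at an unadjusted p under 0.05 there were 9 higher and 71 lower in ENRI only, 39 and 46 in WENRC only, and 9 and 68 in both. DESeq2 called 7 higher and 24 lower in ENRI only, 37 and 4 in WENRC only, and 8 and 12 in both, and edgeR's quasi-likelihood test called 0 in each class without the block. With the block it called 1 higher and 3 lower in ENRI only, 12 and 1 in WENRC only, and 2 and 2 in both.

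The ENRI-only class passed camera (adjusted p = 1.85e-04, adjusted p = 0.412 with an estimated correlation) and lay below all 10000 random gene sets matched on transcription level. Random sets treat genes as independent, while the estimated correlation within this class was 0.252. The class marked in both media passed as well (adjusted p = 0.0156, adjusted p = 0.412 with an estimated correlation), with 38 of 10000 matched sets as low. Genes marked in WENRC only had 9989 of 10000 sets matched on level, and 9665 of 10000 matched on gene length, as low or lower, the latter inside the central 95%. Their camera direction was up relative to other genes, with a median of −0.11 against −0.21 over all tested genes. The class did not pass (adjusted p = 0.0652, adjusted p = 0.284 with an estimated correlation). This class did pass with the replicate block (adjusted p = 0.0347) and with the narrow lists (adjusted p = 0.00374), and its adjusted p was 0.0174 without the WENRC library of batch 2 and 0.0348 without the ENRI library of batch 1, fits with a lone library in 1 medium. The batch medians were −0.35 and −0.91 for ENRI only, −0.25 and −0.49 for both, and −0.05 and −0.17 for WENRC only. Without the filter on low values neither call remained (adjusted p = 0.277 for ENRI only, and adjusted p = 0.591 with the opposite direction for both). The authors' deposited table had 23 genes higher and 51 lower at an FDR under 0.05 in ENRI only, 88 and 21 in WENRC only, and 49 and 40 in both.

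**Figure D3:**
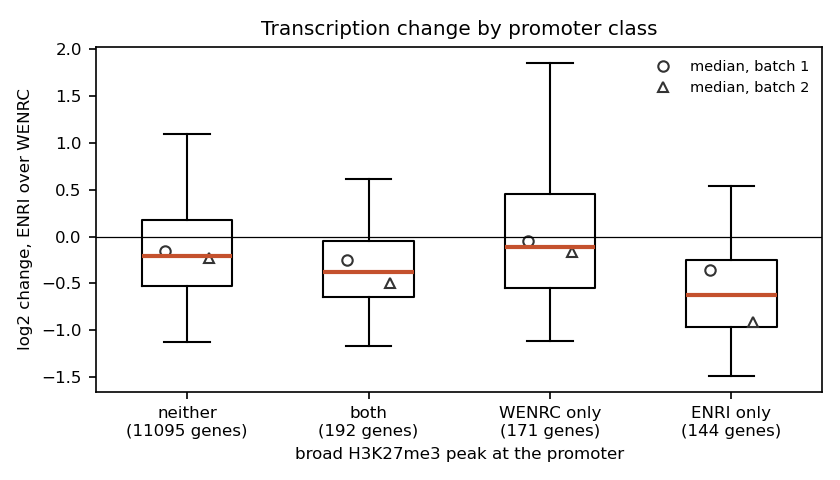
Log2 change in transcription (ENRI over WENRC) of tested genes by the broad H3K27me3 regions at their promoter, with boxes at the quartiles, a line at the median, whiskers from the 5th to the 95th percentile, and medians per batch as circles and triangles. The ENRI-only class of 144 genes has a median of −0.62, against −0.20 for the 11095 genes in neither.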

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

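Alternatives chosen after seeing the data were the filter on at least 10 recovered reads for genes, lists and promoter classes, edgeR's quasi-likelihood test, DESeq2 and edgeR's likelihood ratio test with the replicate block, and the narrow lists for gene lists in promoter classes. Where a result below changed, the cause was not tested. The 17 genes past the test were selected on these data, so a kept direction is no independent check. The 6 microRNA genes among them had 0 reads in ENRI, which leaves little room for a reversal. All 17 kept their direction in all 299 gene and setting pairs and passed in 164. Their number was 1 with pseudocount 0.1, 0 with no filter on low values (limma, 5509 at an unadjusted p under 0.05), 42 with a filter at 1 RPKM, 929 after quantile normalization, 0 with the replicate block (3841), 0 without the trend (4482), 1895 with at least 10 recovered reads and 3638 at an adjusted p under 0.1. It was 0 in edgeR's quasi-likelihood test (3884 at an unadjusted p under 0.05), 2095 in DESeq2 and, with the block, 193 and 1652, and 2507 in edgeR's likelihood ratio test. Leaving out 1 library, with the spread taken from the other medium's pair, gave 0 (either WENRC library, 1685 and 1358 at an unadjusted p under 0.05), 685 (ENRI batch 2) to 5795 (ENRI batch 1). Of the 17 genes, 11 passed with at least 10 recovered reads, in DESeq2 and in each test with the block on reads.

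The 7 lists that passed kept their direction in all 112 list and setting pairs and passed in 98. Among the 98 pairs that used camera with the preset correlation, 97 passed. With an estimated correlation 0 lists passed, with adjusted p = 0.641 for the stem cell, enterocyte, goblet and fatty acid lists, 0.700 for Wnt targets, 0.656 for cell cycle and 0.751 for ribosome biogenesis. With fry, which tests against no change, 2 lists passed, goblet cell and H3K27 demethylase and trithorax (adjusted p = 0.0323). The latter had a median of −0.25, near the −0.21 of all tested genes, and adjusted p = 0.540 in camera, so no difference from other genes was shown. In fry the adjusted p was 0.0637 for the stem cell and cell cycle, 0.0859 for the Wnt target and enterocyte, 0.143 for the fatty acid and 0.119 for the ribosome biogenesis lists. The regenerative list changed direction with fry (0.907), pseudocount 0.1 (0.979), quantile normalization (0.736) and median centring (0.746). With no filter on low values the goblet list no longer passed (0.0720), PRC2 (0.0126) and Notch (0.0296) passed and Hox changed direction (0.953). The Cdkn2 and inhibitor list changed direction with the filter at 1 RPKM (0.897), and PRC2 passed after quantile normalization (0.0496). Leaving out 1 library, the adjusted p ranged from 0.147 to 0.893 for Paneth, 0.0493 to 0.977 for Hox, 0.530 to 0.878 for Cdkn2 and inhibitors, 0.147 to 0.776 for cholesterol synthesis, 2.96e-05 to 0.613 for regenerative and 0.00247 to 0.680 for immediate early genes.

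For the promoter classes, the estimated correlation gave adjusted p = 0.412 for both media and for ENRI only. Without the filter on low values, it was 0.591 for both media, with the direction reversed, and 0.277 for ENRI only. WENRC only passed with the narrow list (0.00374), quantile normalization (0.0490), the replicate block (0.0347) and at least 10 recovered reads (0.0493), and ranged from 0.0174 to 0.136 with 1 library left out. The block changed no other call of a list or class. Promoter counts with the narrow lists were 3389 in both media and 1323 in ENRI only, and 853 were in both with the upper scoring part of the broad lists. Median levels with the narrow lists were 0.0971 RPKM for WENRC only, 0.0356 for ENRI only and 0.623 for neither. Shares of overlapping broad regions were 30.3% of WENRC and 24.1% of ENRI when most of a region had to overlap, and 33.6% and 33.4% with the same number from each list. For narrow peaks they were 26.7% and 14.6%, and 32.1% and 31.9%, and 39.3% of WENRC peaks in the upper scoring part.

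Of 59 tested genes whose transcription the text describes, leaving out those given from the authors' deposited table alone, 5 changed direction in a setting. The named gene Ezh1 had log2 changes of 0.0555 after quantile normalization, 0.0185 and 0.0388 in edgeR's quasi-likelihood test and DESeq2, and 0.0104, 0.0306 and 0.0106 in these and edgeR's likelihood ratio test with the block, while the median of all tested genes moved from −0.21 to −0.04 after quantile normalization and to between 0.0018 and 0.0420 in the other fits. The named gene Ctgf had a log2 change of −0.0181 with pseudocount 0.1, against 0.19 with the pseudocount of 0.5. With 1 library left out, the log2 change ranged from −2.10 to 2.47 for Ctgf, −1.40 to 2.43 for S100a6, −1.42 to 0.28 for Lyz1 and −0.17 to 0.26 for Atoh1. Depth limits genes under 10 reads in WENRC, whose ratios span wide counting intervals.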

Other observations

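The tests of transcription level, gene length, mesenchymal cells and both amino acid response tests, and the 2 lists in the next paragraphs, were chosen only after the results were seen.

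Most genes of the amino acid response, which the transcription factor ATF4 drives when amino acids are scarce or proteins misfold, were lower in ENRI beyond Chac1, Stc2 and Slc7a5. Asparagine synthetase Asns had 3.73 ± 0.162 RPKM in WENRC and 0.654 ± 0.178 RPKM in ENRI (SD, n = 2, log2 change −1.88 ± 0.16), the transcription factor Atf5 7.63 ± 0.991 and 1.26 ± 0.0711 RPKM, and the serine synthesis enzyme Psat1 3.41 ± 0.0399 and 0.401 ± 0.266 RPKM. Without the members past the test, 31 of 33 genes were lower, with a median log2 change of −1.13, and 24 fell when adjusted over the list alone. Not every gene of the response was lower. In the authors' deposited table the log2 change was 0.19 for Ddit3, 0.765 for Cebpg, 0.08 for Cebpb and 0.14 for Slc3a2. These 4 values come from the authors' edgeR fit and not from the limma fit behind the count of lower genes, so signs may differ between them. Camera's unadjusted p-value was 1.17e-07 with the preset correlation and 0.0362 with an estimated correlation. The list was written after the results had prompted it, so these values are descriptive and no independent test.

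Regenerating islet-derived (Reg) genes, secreted lectins of the gut and pancreas, had higher values in ENRI beyond Reg3b, Reg3d and Reg3g, which rose. Reg1 had 1.59 ± 1.46 RPKM in WENRC and 85.6 ± 26.3 RPKM in ENRI (SD, n = 2, log2 change 5.53 ± 0.61), and Reg3a 0.0518 ± 0.0733 and 4.26 ± 1.57 RPKM (3.07 ± 0.27). The 5 tested members had a median log2 change of 3.52, with 3.49 in batch 1 and 3.56 in batch 2. Reg3b, Reg3d and Reg3g had drawn attention to the family and are 3 of these 5 members, so no set test is given.

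The lower amino acid response genes were tested against a difference in 1 batch alone. In the batch where it was smaller, the median of the 33 genes still lay −0.93 from that of all tested genes (−1.09 and −1.18 in the batches, against −0.16 and −0.24), which argues against that. Their median of −1.13 lay below the central range of sets matched on level (lower bound −0.40), which treat genes as independent. These values describe a lower amino acid response in ENRI, as a hypothesis found and tested on the same data, and do not explain it. Whether the medium or the differentiated state accounts for it stays open.

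Regenerative genes had opposite signs in the batches for 14 of 14 members after quantile normalization (medians 1.29 and −1.90), which argues against the scaling of the libraries. Mesenchymal list genes had a median of 0.00712 RPKM in ENRI batch 1, where the regenerative genes had 10.6 RPKM against 3.06, 3.97 and 0.346 RPKM in WENRC batch 1, WENRC batch 2 and ENRI batch 2, which argues against mesenchymal cells. No other biological explanation was tested, and a difference between the mice, cultures or days stays open.

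Tested genes marked in ENRI only had a median log2 change of −0.62, below the lower bounds of sets matched on transcription level (−0.35) and on gene length (−0.31). The sets treat genes as independent, while the estimated correlation within the class was 0.252, so these bounds are too narrow. With an estimated correlation camera gave adjusted p = 0.412. The sets therefore cannot decide whether level or length is the whole cause. They were drawn from genes past the same filter on low values. The class median was −0.03 without a filter and −0.80 with a filter at 1 RPKM (83 genes), and the filter was not tested as a cause. Without members of the Wnt target and stem cell lists the median was −0.61 (138 of the 144 genes, lower bound −0.35). Leaving out so few genes could hardly move a median. The comparison therefore cannot decide whether Wnt or stem cell genes, listed or not, carry the lower median. Genes in this class by both peak lists, which come from the same library, had −0.72 (78 genes), and genes in both media by the narrow list −0.52 (60 genes, 1 of 10000 matched sets as low), so the shift was not limited to promoters whose mark differed by both lists. For WENRC only, genes placed there by both lists had a median of 0.23 (83 genes, 0 of 10000 matched sets as high), and genes in both media by the narrow list −0.30 (79 genes, 1904 of 10000 as low). Whether the mark and transcription move in opposite ways between the media stays open, as the mark rests on 1 library per medium.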
